A study of Mus musculus with 13 samples.

How the data were processed

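Poly(A) RNA from dissected right cortices of perfused mice was sequenced as paired-end reads in 13 libraries: 6 of WT mice given water, 3 of APP/PS1 mice given water and 4 of APP/PS1 mice given trazodone. Per the labels, the instrument was either a NextSeq or a NovaSeq, and which library ran on which is not given. Per the submitters' processing notes, the authors used fastp, STAR and DESeq2 with the GRCm38 (mm10) genome; their versions and the annotation release are not given in the sources used here. The authors deposited a table of FPKM (fragments scaled by gene length and library size) and a table of TPM (length-scaled transcript shares), per the file headers, each with 53832 gene entries and 1 column per library. The deposited TPM equal the deposited FPKM divided by each library's FPKM sum and rescaled, with a largest difference of 0.0087 TPM.

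Of the entries, 25412 carry merged transcript-model IDs (MSTRG) and 28420 carry versioned Ensembl IDs, of which 28028 match GENCODE M21 with their version. Coordinates, biotypes, GC content and transcript length were taken from GENCODE M21 by gene symbol, which stands in for the unnamed release of the authors. A merged model can include a neighbouring gene that has no entry of its own, and 1126 of 22028 protein-coding symbols (5.10%) have no entry. These, including Ctsd, Irf9, Aldh1l1, Glul, mt-Nd4 and mt-Co3, were not analysed here. Where a symbol stood on more than 1 entry (83 symbols), the entry with the highest mean TPM represented it in the gene lists. The tables give no read totals, so depth was estimated from the step of 1 fragment in FPKM multiplied by length, over 2418 single-exon genes of at least 1000 bp.

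Genes with a mean of at least 0.5 TPM over the 13 libraries (18612 genes) were analysed as log2(TPM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), in a single fit of all 3 groups without a block. Each contrast was two-sided, with Benjamini-Hochberg adjusted p under 0.05 called a change; values are log2 fold changes ± SE of that fit and TPM as mean ± SD. Gene lists, 38 in all, were fixed by symbol; the 35 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, so its direction is relative to them. Each list's score, the mean log2(TPM + 0.5) of its members in a library, was compared by an exact two-sided permutation test (84, 35 and 210 splits; smallest p 0.0119, 0.0286 and 0.00476). List counts adjusted over the list alone use the same limma p-values. The lists, the tests, the thresholds and the alternatives were chosen before the data were examined, except for a correction for GC content and length and a rescaling that also leaves out nuclear copies of mitochondrial genes, both added after seeing the data. The comparison of the share of genes moved toward WT with other splits was also added then.

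Genes named in the text followed a rule. In the comparisons of APP/PS1 water with WT water and of APP/PS1 trazodone with APP/PS1 water, it took the 8 called genes with the largest log2 fold change in each direction (mean TPM of at least 1, predicted genes left out), up to 4 members of each called list with the smallest p, and at most 2 members of other lists. App, Prnp, Il1rl1 and Il33 were among the genes always included, and the comparison of APP/PS1 trazodone with WT water took the 5 largest in each direction. Il1rl1 lies below the TPM minimum, so it was tested by exact permutation and in a limma fit with a minimum of 0.1 TPM, chosen before the data were examined.

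The correction for GC content and length subtracted, in each library, a loess trend (span 0.4) of its deviation from the mean of all libraries on GC content and log2 length, over the 18253 tested genes with both values. The share of genes called in APP/PS1 water against WT water whose trazodone mean lay on the WT side was compared with all 35 splits of the 7 APP/PS1 libraries, with genes called anew in each. The correlation of fold changes that share the WT libraries was compared with 100 simulations of unchanged groups and with 20 splits of the WT libraries into separate sets of 3. Alternatives were pseudocounts of 0.1 and 1, minimums of 0.1 and 1 TPM or none, FPKM, median-ratio and quantile scaling, rescaling without mitochondrial, ribosomal protein and hemoglobin genes, robust eBayes, array weights, fits of the 2 groups compared, blocks on the numbers in sample titles or library names, other thresholds and leaving out each library. Of 10 pairs of samples in different groups with the same title number, 2 correlated above 0.1 (mean r 0.0299, other pairs -0.00681), so they share only a number and no block was used. On simulated data with 100 genes changed at each size, the limma steps found 73.0%, 78.0% and 87.0% of genes with a true log2 fold change of 1 and 42.0%, 29.0% and 49.0% of those with 0.5 in the 3 comparisons, with 7.30%, 7.00% and 3.50% false calls. A GC trend was also added to simulated APP/PS1 water libraries, and APP/PS1 trazodone was compared with them. Without the correction 1569 unchanged genes were called, and 9 with it. Of the truly changed genes, 84.0% were found without the correction and 73.5% with it, so it can also lose true changes. The trend was a straight line in GC content, which the correction is built to remove. Figures and depth estimates used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.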

Results

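The series holds 13 poly(A) RNA-seq libraries of mouse cortex: WT mice given water (n = 6), APP/PS1 mice given water (n = 3) and APP/PS1 mice given trazodone (n = 4). APP/PS1 mice are a transgenic model of Alzheimer's disease that carries human APP, and trazodone is an antidepressant that blocks serotonin receptors and serotonin reuptake. Sample titles state 2 weeks; the APP/PS1 line and the dose are not given in the sources used here, and no WT group received trazodone. Each library was treated as 1 animal. Estimated depth ran from 30.6 to 36.8 M fragments. Its means were 33.0 ± 0.408 (SD) M in WT water, 31.5 ± 0.781 M in APP/PS1 water and 35.3 ± 1.33 M in APP/PS1 trazodone, and 16234 to 16835 genes reached 1 TPM per library. The APP/PS1 water libraries stood apart in the trend of log2 TPM on gene GC content: the slope per 10 percentage points was -0.196 ± 0.0365 (SD), against 0.0390 ± 0.0493 in WT water and 0.0881 ± 0.0506 in APP/PS1 trazodone. Mitochondrial genes and their nuclear copies held 21.1 ± 1.05% of TPM in APP/PS1 water, 15.0 ± 2.09% in WT water and 14.6 ± 1.29% in APP/PS1 trazodone.

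The comparison of APP/PS1 water with WT water asks what the genotype changed in the cortex. Genes of plaque-associated microglia, complement and lysosomes were higher in the 3 APP/PS1 water libraries than in the 6 WT libraries. Immediate early genes had 15 of 20 members lower, with a list call that was lost with an estimated correlation (adjusted p = 0.298). Cst7, a cystatin expressed by plaque-associated microglia (MSTRG.13260, GRCm38 chromosome 2, 150570415 to 150578944), rose from 0.291 ± 0.377 to 120.2 ± 54.6 TPM, a log2 fold change of 7.27 ± 0.38 (SE; n = 3 and 6). Gfap, the intermediate filament of reactive astrocytes, rose from 152 ± 34.4 to 946 ± 49.3 TPM. Npas4, a neuronal transcription factor induced by activity, fell from 32.5 ± 6.72 to 9.85 ± 2.87 TPM. Across 18612 genes, 1153 rose and 3260 fell (limma, adjusted p under 0.05), of which 242 rose and 189 fell at least 2-fold.

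Genes linked to the transgenes were measured as well. App (MSTRG.9156, chromosome 16, 84949685 to 85173766), to which reads of a human APP transgene can align, measured 905 ± 121 TPM in WT water and 1928 ± 188 in APP/PS1 water (log2 fold change 1.10 ± 0.11, adjusted p = 2.12e-05). Prnp (MSTRG.13142, chromosome 2), the prion protein gene whose promoter drives transgenes in some APP/PS1 lines, rose from 912 ± 37.6 to 3254 ± 79.6 TPM (1.84 ± 0.06); its model overlaps Prn, which has no entry of its own. The adjacent pseudogene Lamr1-ps1 was listed at 0 in all 6 WT libraries and at 36.3 ± 4.51 TPM in APP/PS1 water.

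Microglial genes rose together. Of 28 measured plaque-associated (DAM) microglial genes, 21 rose, 0 fell and 7 did not pass, and 26 rose when adjusted over the list alone. The median log2 fold change was 1.48 (camera adjusted p = 2.89e-30, adjusted p = 0.0158 with an estimated correlation). Clec7a, a pattern-recognition receptor, rose by 5.07 ± 0.20, Itgax by 4.75 ± 0.22, Trem2, a lipid-sensing receptor, by 2.69 ± 0.13 and Cd68 by 2.24 ± 0.10. The Itgax and Cd68 models have neighbours without entries of their own (Itgad and Tnfsf13). The list's mean score rose from 4.06 ± 0.08 (SD) in WT water to 5.93 ± 0.29, by 1.87 (95% interval 1.62 to 2.12; exact permutation p = 0.0119, the smallest of 84 splits). Among 18 homeostatic microglial genes, 11 rose and 0 fell (13 adjusted over the list alone), including Gpr34 at 2.16 ± 0.15 and Csf1r at 1.06 ± 0.10 (list adjusted p = 4.72e-14, and adjusted p = 0.0163 with an estimated correlation). Complement and Fc receptor genes had 12 of 20 higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 4.72e-14, and adjusted p = 0.0158 with an estimated correlation). C4b, a classical complement gene, rose by 2.85 ± 0.20, C3ar1 by 2.16 ± 0.13 and Fcer1g by 2.10 ± 0.15. Lysosomal genes had 16 of 26 higher and 1 lower (16 and 3 adjusted over the list alone; adjusted p = 4.72e-14, and adjusted p = 0.0158 with an estimated correlation). The hydrolase genes Gusb and Hexa rose by 1.14 ± 0.07 and 0.89 ± 0.07, and the membrane protein gene Lamp2 by 0.76 ± 0.06. Of 14 cytokine and inflammasome genes, 9 rose and 0 fell (11 adjusted over the list alone; adjusted p = 2.87e-11, and adjusted p = 0.0234 with an estimated correlation). Among them were the chemokine genes Ccl3 (4.17 ± 0.24), Ccl4 (2.71 ± 0.31) and Cxcl16 (1.29 ± 0.19).

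Of 27 interferon-response genes, 15 rose and 0 fell (18 adjusted over the list alone, camera adjusted p = 2.30e-12, but adjusted p = 0.147 with an estimated correlation). They included Lgals3bp (1.76 ± 0.23) and the interferon-induced Ifi44 (1.86 ± 0.31) and Ifit3 (0.82 ± 0.14). Antigen presentation had 3 of 18 genes higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 6.95e-04, adjusted p = 0.271 with an estimated correlation). B2m, the light chain of MHC class I, rose by 1.44 ± 0.18 and the immunoproteasome gene Psmb8 by 0.89 ± 0.12. Reactive astrocyte genes had 10 of 26 higher and 0 lower, 10 and 0 adjusted over the list alone (camera adjusted p = 6.80e-08, adjusted p = 0.0953 with an estimated correlation). Gfap rose by 2.66 ± 0.17, the protease inhibitor gene Serpina3n by 2.27 ± 0.18 and Aspg by 1.39 ± 0.16. Among 13 astrocyte markers, 4 rose and 0 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.00319, adjusted p = 0.205 with an estimated correlation). They included the water channel gene Aqp4 at 0.89 ± 0.13 and S100b at 0.47 ± 0.08. Cytosolic ribosomal protein genes had 16 of 40 higher and 5 lower (17 and 6 adjusted over the list alone; camera adjusted p = 2.19e-05, adjusted p = 0.383 with an estimated correlation), and Rpl39 rose by 0.74 ± 0.09. In the cholesterol synthesis list 3 of 23 genes rose and 3 fell (5 and 3 adjusted over the list alone). Stard4, a sterol transfer protein gene, rose by 0.55 ± 0.07. The list's camera adjusted p was 0.0126, against an adjusted p = 0.383 with an estimated correlation, and 0.0621 without WT water 6 or 0.0695 without APP/PS1 water 1.

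Of 20 immediate early genes, 15 fell and 0 rose, with equal counts adjusted over the list alone (median -1.03, camera adjusted p = 1.56e-06, adjusted p = 0.298 with an estimated correlation). The activity-induced transcription factor gene Junb was -1.83 ± 0.24, Egr4 -1.80 ± 0.22, Npas4 -1.69 ± 0.20 and Fos -1.42 ± 0.22. Of 14 excitatory neuron markers, 9 fell and 0 rose, with equal counts adjusted over the list alone (camera adjusted p = 0.00442, adjusted p = 0.297 with an estimated correlation). Emx1, a cortical transcription factor gene, was -1.09 ± 0.17 and Slc17a7, the vesicular glutamate transporter gene, -0.49 ± 0.09. Among 25 synaptic genes, 11 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.0120, adjusted p = 0.383 with an estimated correlation). The scaffold gene Shank1 (-0.84 ± 0.11) and the vesicle release gene Cplx1 (-0.51 ± 0.07) fell, and Rims1, an active zone gene, rose (0.71 ± 0.10). Striatal markers, which a cortical dissection can carry, had 7 of 14 lower and 0 higher (10 lower adjusted over the list alone; camera adjusted p = 0.00319, adjusted p = 0.553 with an estimated correlation). Examples were the opioid peptide gene Penk (-1.03 ± 0.21) and Rgs9 (-1.49 ± 0.33). Of 16 receptor and transporter genes that trazodone or serotonin act on, 7 fell and 0 rose (8 lower adjusted over the list alone), with the adrenergic receptor genes Adra1d at -0.71 ± 0.15 and Adra1b at -0.44 ± 0.11. That camera call (adjusted p = 0.0342) had an adjusted p = 0.315 with an estimated correlation, 0.0757 without WT water 6, 0.0691 without APP/PS1 water 1 and 0.0628 after the GC and length correction. Of these groups, the GC and length correction left 11 of the immediate early genes, 1 excitatory marker, 5 synaptic genes, 2 striatal markers and 1 receptor gene lower. Emx1 was then -0.57, Slc17a7 -0.23, Shank1 -0.35, Adra1d -0.22 and Adra1b -0.23. Camera still called the immediate early (adjusted p = 4.18e-08), excitatory (0.00707), synaptic (0.00707) and striatal lists (0.000273) lower after the correction. With an estimated correlation these lists had adjusted p from 0.290 to 0.370. Mitochondrially encoded mRNA had 4 of 10 members higher and 0 lower (7 higher adjusted over the list alone; median 0.60, camera adjusted p = 5.40e-06, adjusted p = 0.187 with an estimated correlation). The median, positive under the other scalings, turned to -0.04 under quantile normalization. That scaling gives every library the same values rank by rank. It can remove a difference among the most abundant RNAs by construction, so it does not decide this one. mt-Nd6 rose by 0.91 ± 0.16 and mt-Nd3 by 0.70 ± 0.10. mt-Nd3 lies 69 bp from mt-Co3, which has no entry of its own.

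The largest changes also included Rps2-ps10, a ribosomal pseudogene (6.24 ± 1.61), the DAM microglial gene Ccl6 (3.77 ± 0.38) and Eif3j2 (3.38 ± 0.79) upward. Rps2-ps10 ranged from 476 to 876 TPM in APP/PS1 water and from 2.80 to 4.23 in 5 WT libraries, but was 394 in WT water 1. Downward, the largest changes included the Mir212 entry (-2.34 ± 0.21), Krt20 (-2.11 ± 0.46), the ATP synthase gene Atp5k (-1.99 ± 0.16) and the Mir199a-1 entry (-1.93 ± 0.31). Vill (-2.06 ± 0.59), Pcdhb19 (-2.10 ± 0.71) and the Mir1970 entry (-1.84 ± 0.52) were also lower, but leaving out APP/PS1 water 3 or another library ended these calls (adjusted p up to 0.0979, 0.201 and 0.0855). Pcdhb19 overlaps Gm42416, which has no entry of its own. A poly(A) value of a microRNA entry is not a measure of the mature microRNA. Nuclear-encoded respiratory chain genes had no list call, with 10 of 31 lower and 1 higher (12 and 1 adjusted over the list alone); Uqcrh, a complex III gene, was -0.56 ± 0.08. After the GC and length correction camera called this list (adjusted p = 0.0134) and the inhibitory neuron markers (0.0371) lower, with an adjusted p = 0.664 and an adjusted p = 0.290 with an estimated correlation. Other lists without a call included the inhibitory neuron markers (4 of 15 lower), the oligodendrocyte and myelin (1 of 16 lower), oligodendrocyte precursors (2 of 10 lower), mural cell (1 of 12 lower) and hippocampal and thalamic markers (1 of 10 lower). Endothelial (15 genes), fibroblast and meningeal (15), choroid plexus (11), border macrophage (10) and blood leukocyte markers (6) had 0 genes called, as did 4 erythroid markers, which were not tested as a set. Leaving out 1 library made calls of the respiratory chain (adjusted p = 0.00224 without APP/PS1 water 3), inhibitory (0.0126) and endothelial lists (0.032), and of the border macrophage list without APP/PS1 water 1 (0.0314). Xist, the measured member of the sex-linked list, was -0.54 ± 0.20 (adjusted p = 0.0686, and 0.0104 after the GC and length correction), and it was called without APP/PS1 water 1. After the GC and length correction, chosen after seeing the data, 1164 genes rose and 1150 fell, of which 1833 were among the 4413 called without it in the same direction. With median-ratio scaling, 2045 rose and 2032 fell, since it shifts the median of all genes from -0.10 to -0.005. By camera, 17 of 35 lists had a call, and 5 held with an estimated correlation: DAM microglia, homeostatic microglia, complement, lysosome and cytokines. Fry called 19 lists, and by exact permutation of list scores 16 passed adjustment. The inhibitory neuron markers, without a camera call, were among both (fry adjusted p = 0.00102, exact permutation adjusted p = 0.0283). Their score differed by -0.319 (95% interval -0.472 to -0.166).

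**Figure D1:**
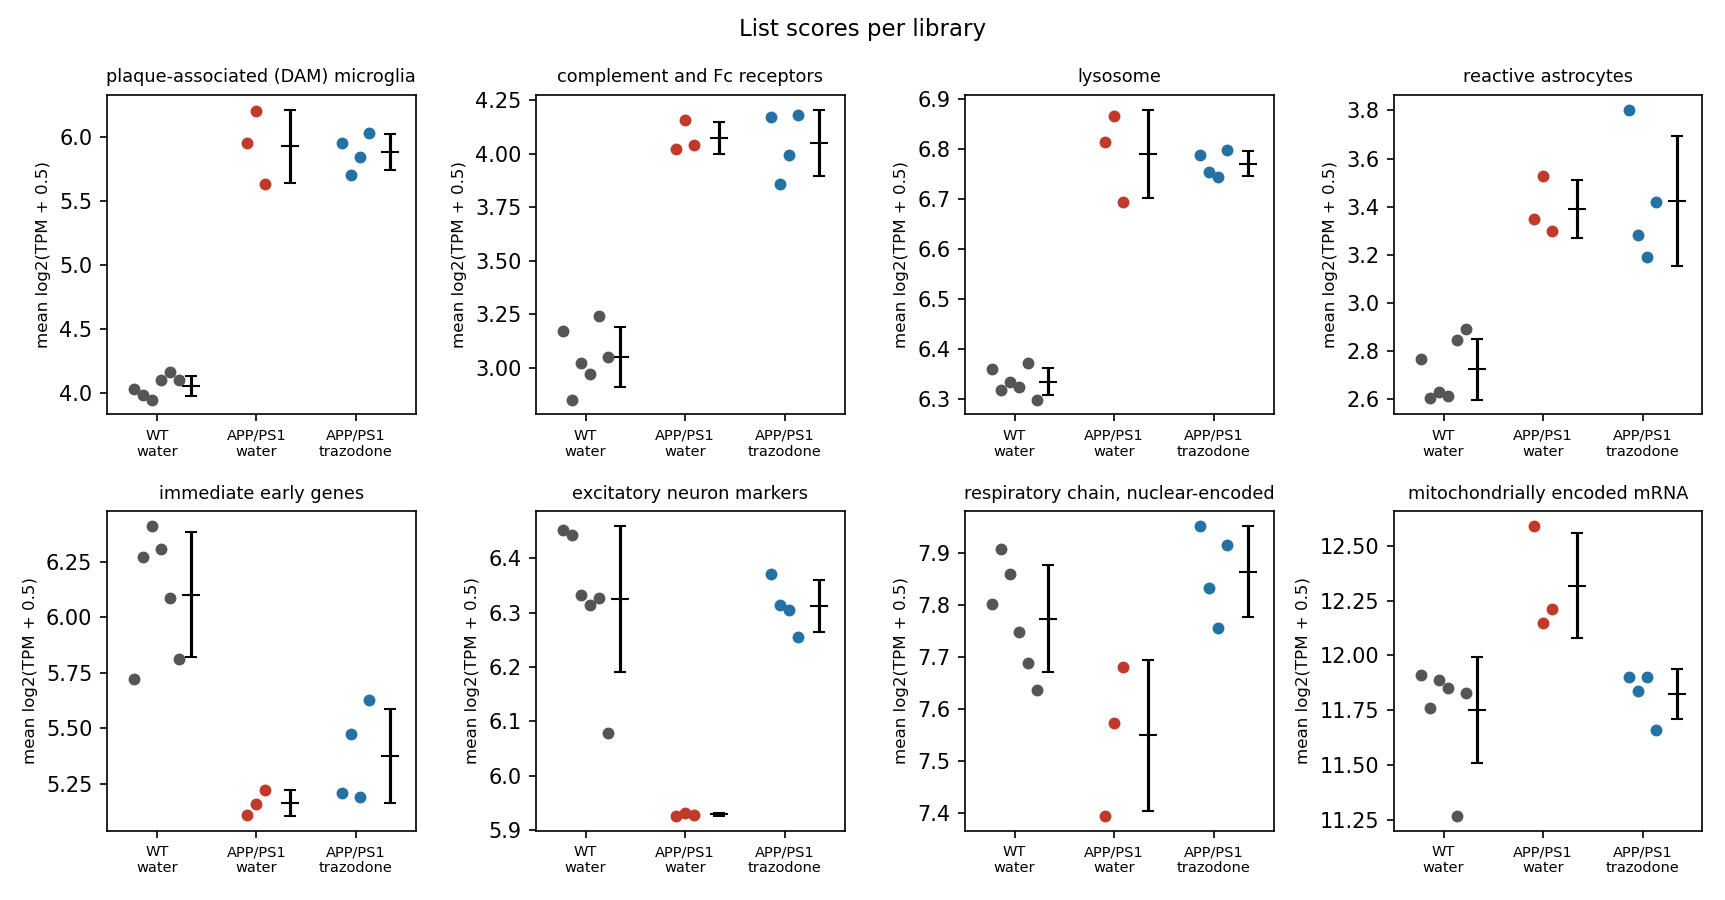
Mean log2(TPM + 0.5) of the measured members of 8 gene lists in each library, by group; points are libraries and bars are mean ± SD. DAM microglia scores were 5.93 ± 0.29 in APP/PS1 water and 5.88 ± 0.14 in APP/PS1 trazodone against 4.06 ± 0.08 in WT water. The mitochondrial median of APP/PS1 water against WT water turned to -0.04 under quantile normalization, which equalizes the most abundant RNAs by construction.

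The comparison of APP/PS1 trazodone with APP/PS1 water asks what trazodone changed in APP/PS1 mice. In the 4 trazodone libraries, 10 of 31 nuclear-encoded respiratory chain genes and 8 of 14 excitatory neuron markers were higher than in the 3 water libraries, and 6 of 10 mitochondrially encoded mRNAs were lower. These 3 list calls were lost with an estimated correlation (adjusted p = 0.913 each), and plaque-associated microglial, complement and reactive astrocyte genes differed little. Atp5k, an ATP synthase subunit gene (MSTRG.17511, chromosome 5), rose from 26.8 ± 7.01 to 124 ± 10.4 TPM, a log2 fold change of 2.21 ± 0.17. Tmsb10, an actin-binding thymosin gene (MSTRG.18944, chromosome 6), rose from 169 ± 15.4 to 655 ± 61.9 TPM (1.95 ± 0.14). Mt1, a metallothionein gene, fell from 1166 ± 137 to 754 ± 77.4 TPM (-0.63 ± 0.10). Across 18612 genes, 2319 rose and 730 fell (limma, adjusted p under 0.05), of which 177 rose and 36 fell at least 2-fold. After the GC and length correction, 476 rose and 288 fell, of which 595 were among the 3049 called without it in the same direction; median-ratio scaling gave 1618 higher and 1394 lower.

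Of 31 nuclear-encoded respiratory chain genes, 10 rose and 0 fell (11 adjusted over the list alone; median 0.19; camera adjusted p = 0.0143, adjusted p = 0.913 with an estimated correlation). Besides Atp5k, the subunit genes Cox8a (0.93 ± 0.12), Atp5e (0.77 ± 0.10) and Uqcrh (0.67 ± 0.08) rose. After the GC and length correction they were 0.62, 0.68 and 0.66, and Atp5k 1.98, with 7 of the list's genes called higher. The list's score rose from 7.55 ± 0.15 to 7.86 ± 0.09, by 0.31 (95% interval 0.13 to 0.50; exact permutation p = 0.0286, the smallest of 35 splits). Its camera call ended without APP/PS1 water 1 (adjusted p = 0.341) and under median-ratio scaling (0.0904). Of 14 excitatory neuron markers, 8 rose and 0 fell, with equal counts adjusted over the list alone (median 0.38, camera adjusted p = 0.0182, adjusted p = 0.913 with an estimated correlation). Emx1 rose by 1.23 ± 0.19, the transcription factor gene Neurod2 by 0.57 ± 0.08 and Nrgn, a postsynaptic calmodulin-binding gene, by 0.83 ± 0.19. After the correction these were 0.64, 0.22 and 0.49, and 1 of the 14 markers was called. Other lists without a camera call also scored higher. Synaptic genes, 9 of 25 higher and 3 lower (3 and 1 after the correction), differed by 0.181 (95% interval 0.057 to 0.305). Inhibitory neuron markers differed by 0.192 (0.027 to 0.357) and mural cell markers by 0.327 (0.052 to 0.601). Endothelial markers did not (-0.012, -0.221 to 0.197). These intervals are of uncorrected scores and are not adjusted over lists. After the correction camera called the excitatory list (adjusted p = 0.00429), but not the synaptic (0.179), inhibitory (0.671) or mural lists (0.298). With an estimated correlation each had an adjusted p of 0.988. Whether the rise was particular to excitatory markers is therefore not settled. Among mitochondrially encoded mRNA, 6 of 10 fell and 0 rose, with equal counts adjusted over the list alone (median -0.54, camera adjusted p = 6.20e-05, adjusted p = 0.913 with an estimated correlation). After the correction 0 were called, the median was -0.24 and the list's adjusted p was 0.108. Quantile normalization, which equalizes the most abundant RNAs by construction, turned mt-Nd2 from -0.71 to 0.09. The mitochondrial share of TPM and the GC slope of the libraries moved with these groups, as given above.

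Plaque-associated and inflammatory groups had no call. Of 28 DAM microglial genes, 1 fell and 1 rose (0 and 0 adjusted over the list alone); the score differed by -0.05 (95% interval -0.32 to 0.23). The camera adjusted p was 0.410, but 0.0191 without APP/PS1 water 3 and 0.0403 without APP/PS1 trazodone 4. The lower gene was Clec7a (-0.69 ± 0.22, adjusted p = 0.0449) and the higher one Apoe, a lipid carrier gene (1.04 ± 0.33, adjusted p = 0.0491). Leaving out any of 9 and 10 libraries ended these calls, with adjusted p up to 0.172 without APP/PS1 water 2 and 0.178 without APP/PS1 water 3, and the correction gave -0.51 and 0.68. Homeostatic microglial genes had 2 of 18 lower, also adjusted over the list alone, with Gpr34 at -0.77 ± 0.17 (-0.48 after the correction). The list's camera adjusted p was 0.0610, and between 0.0163 and 0.0479 without WT water 2, APP/PS1 water 3, APP/PS1 trazodone 3 or APP/PS1 trazodone 4. Complement and Fc receptor genes had 2 of 20 lower, also adjusted over the list alone, with a score difference of -0.02 (95% interval -0.25 to 0.21). Fcer1g, an Fc receptor chain gene, was -0.66 ± 0.16, with an adjusted p of 0.0144 that became 0.0724 without APP/PS1 water 2. Lysosomal genes had 3 of 26 lower and 1 higher (3 and 2 adjusted over the list alone), with Lamp2 at -0.43 ± 0.07 (-0.19 after the correction) and a score difference of -0.02 (95% interval -0.10 to 0.06). After the correction the lysosomal and homeostatic microglial lists were called lower by camera (adjusted p = 0.000671 and 0.0108), beside the respiratory chain and excitatory lists called higher; all 4 then had an adjusted p = 0.988 with an estimated correlation. Reactive astrocyte genes had 1 of 26 higher and 1 lower (0 and 0 adjusted over the list alone; score difference 0.03, 95% interval -0.28 to 0.34), and interferon-response genes had 0 of 27 called. Of 14 cytokine and inflammasome genes, 1 rose and 1 fell, with equal counts adjusted over the list alone: Il18, an inflammasome cytokine gene, fell (-0.56 ± 0.09, -0.52 after the correction) and Tgfb1 rose (0.37 ± 0.10, 0.20 after it, adjusted p = 0.292; 0.110 without APP/PS1 water 3). Antigen presentation had 1 of 18 higher, also adjusted over the list alone: Tapbp, a peptide-loading gene (0.65 ± 0.12, 0.36 after the correction, adjusted p = 0.0859). Tapbp overlaps Zbtb22, which has no entry of its own, so its value may include reads of that gene. Immediate early genes had 3 of 20 higher and 0 lower, with equal counts adjusted over the list alone; Npas4 was 0.97 ± 0.22 (0.71 after the correction, adjusted p = 0.109).

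App measured 2702 ± 185 TPM under trazodone, higher than in APP/PS1 water by 0.49 ± 0.12 on the log2 scale (adjusted p = 0.0138; 0.0602 without APP/PS1 water 3), and 0.52 after the GC and length correction. Prnp was 3057 ± 153 TPM (-0.09 ± 0.07, adjusted p = 0.399). Cck, a member of the inhibitory neuron list, rose by 0.91 ± 0.15 (0.64 after the correction). That list had 2 of 15 genes higher and no camera call (adjusted p = 0.550), and bulk values do not assign the rise to a cell type. Among the largest changes, Bex3 (1.72 ± 0.16), Atp6v0c, a proton pump subunit gene (1.68 ± 0.35), and the Mir212 (2.25 ± 0.23), Mir7030 (1.99 ± 0.36) and Mir6991 (1.75 ± 0.33) entries rose and kept their calls after the correction. Phf24 rose by 1.75 ± 0.46, but was 1.59 (adjusted p = 0.0642) after it. Usf3 (-1.56 ± 0.37), Pkib (-1.16 ± 0.15) and the Mir466i (-1.97 ± 0.40) and Mir665 (-1.29 ± 0.35) entries fell and kept their calls. Rbm12b1 (-1.88 ± 0.59), the brain cytoplasmic RNA Bc1 (-1.68 ± 0.41), Vma21 (-1.60 ± 0.51) and Snord98 (-1.17 ± 0.33) fell too, but had adjusted p from 0.0689 to 0.155 after it. Of these, leaving out 1 library ended the calls of Phf24 (adjusted p up to 0.0665), Rbm12b1 (0.105), Bc1 (0.0600), Vma21 (0.116), Mir665 (0.0706) and Snord98 (0.114).

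By camera, 3 of 35 lists had a call (4 at an unadjusted p under 0.05); with an estimated correlation 0 did, and fry called 2. By exact permutation of list scores 0 lists passed adjustment, with the smallest p at 0.0286 (adjusted p = 0.181). Treatment coincides with any unlabelled batch of the 3 APP/PS1 water libraries, so these 2 are not separable here.

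**Figure D2:**
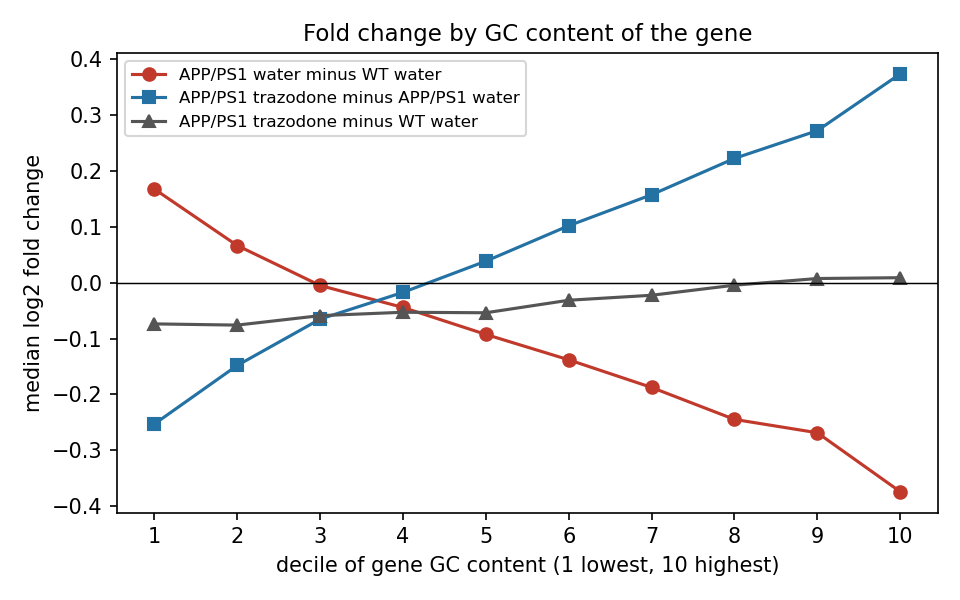
Median log2 fold change of genes in deciles of GC content (x axis, 1 lowest to 10 highest) for each comparison. The median ran from 0.17 in the lowest to -0.37 in the highest decile for APP/PS1 water minus WT water, and from -0.25 to 0.37 for APP/PS1 trazodone minus APP/PS1 water.

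The comparison of APP/PS1 trazodone with WT water asks where treated APP/PS1 mice stand relative to WT. Microglial, complement, lysosomal and reactive astrocyte genes were higher in APP/PS1 trazodone (n = 4) than in WT water (n = 6). Of 20 immediate early genes, 7 were lower, with a list adjusted p = 0.0561 with an estimated correlation. Cst7 was 106 ± 33.8 TPM under trazodone (7.14 ± 0.35), Itgax 18.4 ± 2.81 (4.48 ± 0.20), Clec7a 18.5 ± 4.75 (4.38 ± 0.18) and Ccl3 12.4 ± 0.894 (4.01 ± 0.22). Lamr1-ps1 measured 41.0 ± 6.65 TPM against 0 in all 6 WT libraries. Fos fell from 93.2 ± 20.3 to 39.9 ± 13.1 TPM (-1.24 ± 0.20), Egr2 by 1.49 ± 0.26 on the log2 scale, Apold1 by 1.22 ± 0.20 and the retinoid isomerase gene Rpe65 by 1.46 ± 0.25. Dusp1 was -1.11 ± 0.24, a call that 4 left-out libraries ended (adjusted p up to 0.0802 without APP/PS1 trazodone 1). App (1.59 ± 0.10) and Prnp (1.74 ± 0.06) were higher. Across 18612 genes, 367 rose and 48 fell (limma, adjusted p under 0.05); the GC and length correction gave 407 and 69, with 390 of the 415 called genes called in the same direction.

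Counts adjusted over the list alone follow in parentheses. Higher than WT were 20 of 28 DAM microglial (24), 11 of 18 homeostatic microglial (12), 11 of 20 complement and Fc receptor (14) and 15 of 26 lysosomal genes (15), and 0 were lower. So were 9 of 26 reactive astrocyte (14), 8 of 27 interferon-response (22), 3 of 18 antigen presentation (9) and 6 of 14 cytokine genes (9), and 0 were lower. These 8 of 20 camera calls held with an estimated correlation (adjusted p from 0.00124 to 0.0238). Called higher without that support were ribosomal proteins (adjusted p = 0.0561 with an estimated correlation; 3 of 40 genes, 26 adjusted over the list alone), astrocyte markers (0.0593), cholesterol synthesis (0.0725), border macrophage markers (0.108), mural cell markers (0.284) and the respiratory chain (0.574). Called lower were immediate early genes (7 of 20 genes, 17 adjusted over the list alone; adjusted p = 0.0561 with an estimated correlation), trazodone targets (0.226), synaptic genes (0.435), circadian genes (0.435), striatal markers (0.574) and choroid plexus markers (0.617). Leaving out 1 library ended the preset-correlation calls of 6 of these lists: choroid plexus (adjusted p up to 0.309, without WT water 6), circadian (0.298, without APP/PS1 trazodone 1), striatal (0.131, without APP/PS1 trazodone 2), respiratory chain (0.0966, without APP/PS1 trazodone 4), trazodone targets (0.0935, without APP/PS1 trazodone 1) and border macrophage (0.0667, without APP/PS1 trazodone 4). The GC and length correction ended those of the synaptic (adjusted p = 0.187), respiratory chain (0.112) and circadian lists (0.0802), and called the inhibitory neuron markers lower (0.0273) and the oligodendrocyte precursors higher (0.0254); these 2 had an adjusted p = 0.310 and an adjusted p = 0.216 with an estimated correlation.

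Of the 4413 genes called between APP/PS1 water and WT water, 96.6% had a trazodone mean on the WT side of the APP/PS1 water mean, with a median recovery of 83.9%. Genes chosen with the APP/PS1 water libraries can move toward WT by selection. The other 34 splits of the 7 APP/PS1 libraries had a median share of 66.0% and a highest share of 93.3%. Their median recoveries were 7.16% (median) and 59.9% (highest). These splits mix libraries of both groups and can keep part of the difference between them. They therefore do not give the share that selection alone would produce. No test compared recovery between gene groups. Its median was 87.5% over the 3260 lower genes, of which 1973 rose with trazodone, and 58.0% over the 1153 higher genes, of which 426 fell; with the GC and length correction it was 82.3% over 1150 (410 rose) and 47.2% over 1164 (202 fell). For raised DAM microglial genes it was 5.85%, and 19 of 21 were still called higher than WT; it was 6.63% for complement, 8.66% for lysosomal, 8.08% for reactive astrocyte and 16.2% for homeostatic microglial genes. With the GC and length correction these were 10.9%, 13.9%, 26.8%, 11.8% and 25.4%. For lowered genes it was 110% in the excitatory list, 123% in the respiratory chain, 90.5% in the synaptic list and 29.6% in the immediate early list, of which 7 of 15 were still called lower than WT. After the correction the immediate early list had 10.9%, with 8 of 11 still called lower, the respiratory chain 116% and the synaptic list 95.8%, and the excitatory list had 1 lower gene left. Over all called genes, the corrected share was 95.9% with a median recovery of 68.1% (other splits at most 94.4% and 40.2%). Across genes, which are not independent replicates, the fold changes of both APP/PS1 groups against the shared WT libraries correlated with r = 0.553 (Spearman 0.306), against 0.366 (0.330) in simulated unchanged groups and a median of 0.384 (0.162) with separate WT libraries for each.

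**Figure D3:**
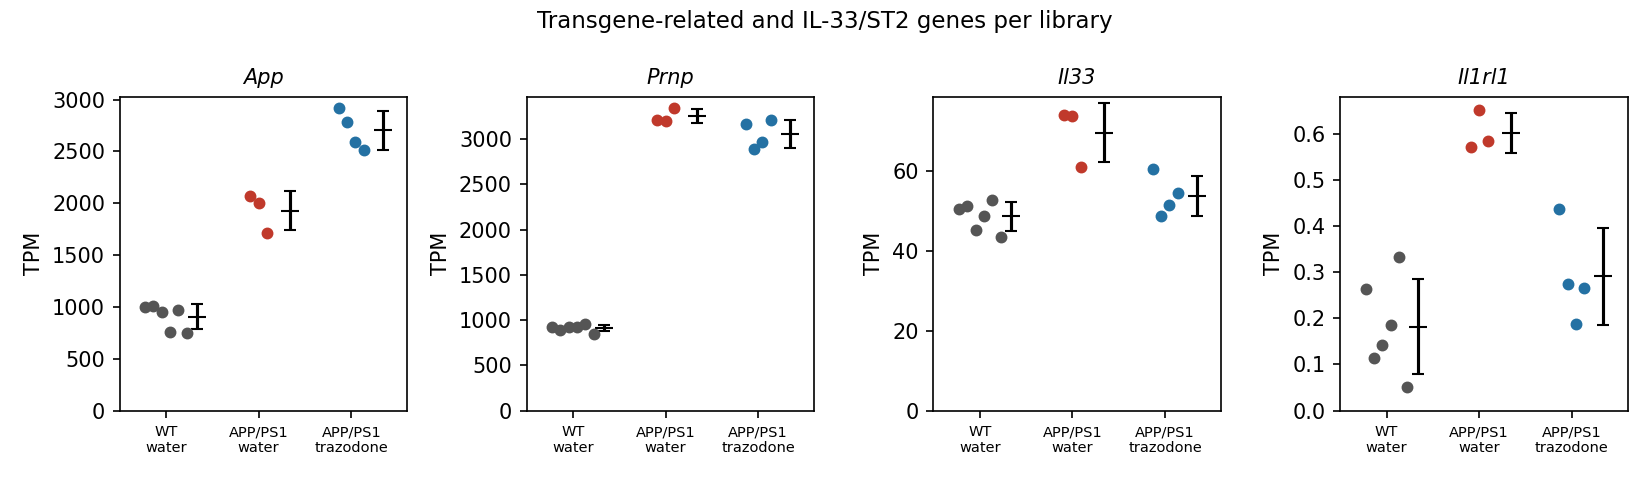
TPM of App, Prnp, Il33 and Il1rl1 in each library by group; points are libraries and bars are mean ± SD. App was 905 ± 121 TPM in WT water, 1928 ± 188 in APP/PS1 water and 2702 ± 185 in APP/PS1 trazodone.

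The series title names soluble ST2, the decoy form of the interleukin-33 receptor encoded by Il1rl1. Il1rl1 (ENSMUSG00000026069.15, chromosome 1, 40429570 to 40465415) measured 0.182 ± 0.103 TPM in WT water, 0.602 ± 0.0431 in APP/PS1 water and 0.291 ± 0.105 in APP/PS1 trazodone, near the lower end of detection. The APP/PS1 water libraries, at 0.571 to 0.651 TPM, lay above all WT (0.0514 to 0.333) and all trazodone libraries (0.188 to 0.437). The exact permutation p was 0.0119 against WT (the smallest of 84 splits), 0.0571 for trazodone against APP/PS1 water (35 splits) and 0.133 for trazodone against WT (210 splits). With a minimum of 0.1 TPM, limma gave adjusted p of 0.0082, 0.0974 and 0.618, and 0.0223, 0.313 and 0.5 after the GC and length correction. The gene-level values do not separate the soluble from the membrane form. Il33, an alarmin gene (MSTRG.11500, chromosome 19), rose from 48.7 ± 3.62 to 69.7 ± 7.37 TPM in APP/PS1 water (0.51 ± 0.09, adjusted p = 0.00109; 0.41 after the correction) and was 53.8 ± 5.05 TPM under trazodone. The trazodone difference was -0.37 ± 0.10 (adjusted p = 0.0183), but -0.25 (adjusted p = 0.162) after the correction, and leaving out APP/PS1 water 1, APP/PS1 water 2 or APP/PS1 trazodone 2 ended the call (adjusted p up to 0.0776). Of 11 measured IL-33/ST2 pathway genes, 1 rose and 1 fell in APP/PS1 water, and 1 of 11 moved each way with trazodone, with equal counts adjusted over the list alone. The genes were Il33 and Rela, an NF-kappa-B subunit gene; Rela was -0.33 ± 0.09 and 0.40 ± 0.10, which became 0.01 and 0.03 after the correction, and its 2 calls ended without APP/PS1 water 3 (adjusted p = 0.116 and 0.0719). The list had no camera call (adjusted p = 0.148 and 0.550).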

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

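The tests of depth, mitochondrial share, genotype alone, nuclear copies, a treatment effect on the GC slope, and the splits behind the share of genes moved toward WT were chosen after the results were seen. The splits of corrected counts use the GC and length correction, itself added after seeing the data, and the remaining tests were written down before their own values were computed. Values far from the rest of their own group were found in 29 of 420 groups tested, and chance picks about 5% of groups. Only WT water and APP/PS1 trazodone were scanned in this way. The 3 APP/PS1 water libraries were not scanned, so outlying values among them are not listed. Bc1, for example, ranged from 2952.4 to 13937.5 TPM there.

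WT water 6 stood apart with 27221 genes above 0 (26079 to 26433 in the other WT libraries) and with choroid plexus genes: Sostdc1 at 30.7 TPM (others at most 6.75), Kcnj13 at 14.5 (5.72), Folr1 at 10.3 (3.59) and Otx2 at 5.97 (1.95). The same library had an excitatory neuron score of 6.08 (others at least 6.31), an inhibitory neuron score of 6.49 (others at most 6.34), Ly6c1 at 69.6 TPM (at most 57.2) and the Mir6991 entry at 3.16 TPM (at least 6.76). Choroid plexus signal was not confined to WT water 6. The list's score was 4.20 there and 2.56 in WT water 3, against at most 0.664 in the remaining WT libraries. WT water 5 had a cytokine score of 1.52 (others at most 1.15), a mitochondrial mRNA score of 11.3 (at least 11.8), and higher Gfap at 219.9 TPM (at most 151), Atp1b2 at 528 (at most 484), Ccl4 at 0.654 (at most 0.195) and Eif3j2 at 4.08 (at most 0.267). Rps2-ps10 measured 394 TPM in WT water 1, where the other WT libraries had at most 4.23, and 4.13 in APP/PS1 trazodone 3, where the others had at least 419. WT water 1 also had high Cd14 at 6.83 TPM (others at most 3.90) and Pcdhb19 at 4.82 (at most 4.06), and WT water 4 had Phf24 at 132 TPM (at most 74.4). APP/PS1 trazodone 3 had high Cd74 at 133 TPM (others at most 40.5), Gpr34 at 51.9 (41.5) and Vma21 at 41.1 (14.1), and low Rela at 22.8 (at least 26.8) and Aplp1 at 1213 (at least 1329). APP/PS1 trazodone 1 had Atp6v0c at 493 TPM (others at least 1087) and Cry2 at 96.4 (at least 107), and APP/PS1 trazodone 2 had an IL-33/ST2 score of 3.91 (at least 4.02) and Sostdc1 at 1.65 TPM (others at most 1.38).

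The fold changes of APP/PS1 water against WT water followed GC content in each of 10 expression deciles, with a weakest rank correlation of -0.273, which describes the trend and does not separate a technical bias from a biological shift. Depth as the cause would need a trazodone minus WT slope of 0.369 in proportion to the depth difference, and it was 0.049 (SE 0.032); a larger mitochondrial share would shift other genes alike, but the top minus the bottom GC decile differed by -0.548 (SE 0.012) without those genes. Genotype alone is argued against by the trazodone libraries, whose lowest slope was 0.027 where the highest of APP/PS1 water was -0.16. A genotype effect undone by trazodone (slope difference 0.284 ± 0.033, SE) and a library batch of the 3 APP/PS1 water libraries cannot be told apart, because treatment and libraries coincide and the instrument of each library is not given.

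Mitochondrially encoded mRNA was higher in APP/PS1 water than in WT water, by a median of 0.60 that turned to -0.04 under quantile normalization. That scaling equalizes the most abundant RNAs of all libraries by construction, so it does not decide whether they differed. The median lay at percentile 99.99 of 10000 lists matched on GC content, whose median was 0.18. After the GC and length correction the mitochondrial median was 0.40, with 3 of 10 genes higher. Camera then gave an adjusted p of 0.00707, and 0.290 with an estimated correlation. With trazodone the median was at percentile 0.24 (-0.54, matched -0.29), but 0 of 10 genes were called after the correction. The matched lists were not matched on TPM or on correlation between genes. For APP/PS1 water against WT water, the rank correlation of fold change with GC content was -0.273 in the lowest TPM decile and -0.582 in the highest. The percentiles therefore do not decide how much of either difference GC bias accounts for. Reads shared with nuclear copies would leave the summed share alike, and it differed by 6.04 percentage points (WT SD 2.09). Genotype alone is argued against by a highest share of 15.72% under trazodone against a lowest of 20.34% in APP/PS1 water, and an effect of trazodone or of RNA handling in those 3 libraries stays open, untested.

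Il33 in APP/PS1 water against WT water lay at percentile 98.3 of genes matched on GC content and TPM, outside their central 95%. Il1rl1 at percentile 95 lay within it. Such a rank also reflects noise and true changes among the matched genes, so it does not decide the cause for a single gene. With the minimum of 0.1 TPM their log2 fold changes of 0.51 and 0.71 were 0.42 and 0.68 after the correction (adjusted p = 0.00841 and 0.0223). With trazodone, Il33 (percentile 6.6) and Il1rl1 (percentile 8.6) both lay within the central 95%, which leaves GC bias open. Their log2 fold changes of -0.37 and -0.49 were then -0.26 and -0.39 after the correction (adjusted p = 0.175 and 0.313). The pseudocount of 0.5 TPM shrinks the log2 fold changes of Il1rl1. Its mean TPM in APP/PS1 water was 3.31 times that in WT water, and under trazodone 0.484 times that in APP/PS1 water. The batch of the APP/PS1 water libraries stays open for both genes, as does an effect of genotype and of trazodone.

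Other splits of the libraries gave few genes: of 84 splits, 1 (the real one) gave as many genes between APP/PS1 water and WT water (4413, highest other 4), and after the GC and length correction again 1 (2314, highest other 8). For APP/PS1 trazodone against APP/PS1 water, 1 of 35 splits gave as many genes (3049, highest other 4; 764 and 4 after the correction), and against WT water 1 of 100 drawn splits (415, highest other 3; 476 and 3 after the correction). The share of genes moved toward WT, 96.6%, was reached by 1 of 35 splits (highest other 93.3%). Chance is not excluded for the numbers of lists: 20 of 84 splits gave at least 17 lists (highest other 23), 33 of 35 gave at least 3 (highest other 14) and 7 of 100 gave at least 20 (highest other 22).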

How the results depend on the processing

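The alternatives named GC and length correction and rescaling also without nuclear mitochondrial copies were chosen after seeing the data; the rest were planned. Under the planned scalings, filters, pseudocounts and fits, total counts of genes and lists stayed within 1.5 times the reported ones except as follows, and the cause was not tested unless stated. For APP/PS1 water against WT water the library-number block gave 2312 genes, an added minimum log2 fold change of 0.5 gave 2077 by its own construction, and the GC and length correction gave 2314; an estimated inter-gene correlation gave 5 lists. For APP/PS1 trazodone against APP/PS1 water the same settings gave 1730, 1315 and 764 genes and 0 lists (against 4 at an unadjusted p under 0.05 with the preset correlation, and 2 by fry), array weights gave 5 lists, and rescaling without mitochondrial, ribosomal protein and hemoglobin genes gave 1 list, as it did also without nuclear copies (1); both leave out the mitochondrial list by construction, and the loss of 1 of the 2 higher lists was not examined. For APP/PS1 trazodone against WT water the library-number block gave 235 genes, an adjusted p under 0.1 gave 651 by its own construction, an estimated correlation gave 8 lists and fry 13. Directions moved more: FPKM gave 1841 higher and 2225 lower genes in APP/PS1 water against WT water and 1882 and 1303 with trazodone, and quantile normalization 2118 and 2071, and 1505 and 1582. The replicate block on title numbers gave 4027, 2872 and 305 genes. The correlation of fold changes was 0.636 after the GC and length correction.

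Leaving out each library gave 3169 (without APP/PS1 water 2) to 4677 genes, 2079 (without APP/PS1 trazodone 2) to 3204 genes and 279 (without APP/PS1 trazodone 1) to 433 genes in the 3 comparisons. It gave 16 to 20, 2 to 5 (without APP/PS1 water 1 and 3) and 16 to 20 lists, a share moved toward WT of 95.5% to 97.0% and a correlation of 0.515 to 0.574. Of the named genes called, 104, 76 and 12 in the 3 comparisons, the GC and length correction kept 77, 30 and 12. Reversed under quantile normalization, which sets all libraries to a common distribution, were mt-Nd2 (-0.094) and mt-Nd4l (-0.089) in APP/PS1 water against WT water and mt-Nd2 (0.094) and mt-Nd4l (0.039) with trazodone. Reversed by the GC and length correction were Rela (0.005) and Adra2c (0.009) in APP/PS1 water against WT water, and Slc32a1 (-0.033), Olig1 (-0.042) and Cebpb (-0.21) with trazodone.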

Other observations

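Values of further stress, clock and metabolic genes follow. The metallothionein genes Mt1 and Mt2 rose in APP/PS1 water (0.89 ± 0.09 and 0.81 ± 0.11) and fell with trazodone (-0.63 ± 0.10 and -0.45 ± 0.12). After the GC and length correction the falls were -0.80 and -0.68, and without APP/PS1 water 2 the adjusted p of Mt2 was 0.103. Among 15 glucocorticoid-responsive genes, 2 rose and 2 fell in APP/PS1 water and 2 fell with trazodone, with equal counts adjusted over the list alone. Ciart, a clock repressor gene, fell in APP/PS1 water (-1.52 ± 0.19) and rose with trazodone (1.10 ± 0.21, 0.94 after the correction), among 16 circadian genes. Of these, 5 fell in APP/PS1 water (6 adjusted over the list alone) and 4 rose with trazodone (4, and 1 lower, adjusted over the list alone); with the GC and length correction 1 was higher and 2 lower, then 1 and 1. The co-chaperone gene Stip1 fell (-0.54 ± 0.08) and rose (0.57 ± 0.09); of 16 heat shock genes 6 fell and 1 rose in APP/PS1 water and 2 rose with trazodone, with equal counts adjusted over the list alone. Corrected counts of that list were 0 higher and 2 lower, then 1 and 0. Of 22 ER chaperone and unfolded protein response genes, 4 rose and 3 fell in APP/PS1 water, and 1 rose and 4 fell with trazodone (2 and 5 adjusted over the list alone); Dnajb9 was 0.33 ± 0.06 and then -0.45 ± 0.06, and after the correction 0.18 and -0.27, with 3 of the list higher and 0 lower, then 0 and 2.

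Of 25 integrated stress response genes, targets of ATF4, 3 rose and 6 fell in APP/PS1 water (3 and 7 adjusted over the list alone) and 5 rose with trazodone (5 adjusted over the list alone). With the GC and length correction 4 were higher and 3 lower in APP/PS1 water, and 1 higher and 1 lower with trazodone. Ddit4 was -0.78 ± 0.12 in the former, and Slc3a2 -0.47 ± 0.09 and then 0.52 ± 0.09. Among 19 genes of amyloid processing and clearance, 1 rose and 3 fell in APP/PS1 water and 5 rose with trazodone, with equal counts adjusted over the list alone. They included Aplp1 (-0.44 ± 0.08) in the former and Bin1 (0.43 ± 0.07) in the latter; after the GC and length correction these were -0.12 and 0.18, and the list had 3 higher and 0 lower in the former and 0 higher and 1 lower in the latter. The cholesterol gene Mvd rose with trazodone (0.78 ± 0.11, 0.43 after the correction), among 4 of 23 genes, also adjusted over the list alone (1 after the correction). Ribosomal protein genes split with trazodone, 10 of 40 higher and 7 lower (11 and 7 adjusted over the list alone, 6 and 7 after the correction), with Rpl35 at 0.94 ± 0.12, and the list had no call (adjusted p = 0.933). These lists had no camera call in APP/PS1 water against WT water or in trazodone against water, except cholesterol synthesis and ribosomal proteins in the former. In APP/PS1 water against WT water, fry called the circadian (adjusted p = 0.00831) and heat shock lists (0.0257). The circadian score also passed exact permutation there (adjusted p = 0.0283), with a difference of -0.320 (95% interval -0.493 to -0.147). After the GC and length correction the circadian median was 0.006. Without APP/PS1 water 1, the ER chaperone (adjusted p = 0.0353) and glucocorticoid lists (0.034) had a call in APP/PS1 water against WT water. Direction of the camera test and of the median differed in lists without a call, such as the oligodendrocyte precursors in APP/PS1 water (median -0.04, test upward), because the test compares with all other genes.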
